A study of Mus musculus with 8 samples.

How the data were processed

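Germinal centre B cells were sorted from lymph nodes of immunized mice by a gate that included B220 and CD95, and then by CXCR4 and CD83 into light zone and dark zone cells, per the labels. RNA was labelled with the Affymetrix 3' IVT Express kit, per the labels' protocols, and hybridised to Affymetrix mouse expression arrays, with 4 arrays for each zone. Samples were grouped by the zone in their titles, and the labels call them biological replicates.

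The table used here holds 45037 probe sets in 8 arrays. The submitters' processing notes name RMA, a method of background correction, quantile normalization and probe summary, with no version given in the sources used here. The deposited values are RMA intensity values on a linear scale, whereas the planned analysis had assumed log2 values. The log2 of the deposited intensity values was therefore taken before every test, with no pseudocount, since no value was missing or at or below 0. No detection calls were used. A quantile normalization of this kind gives every array nearly the same distribution, so a change in total RNA per cell cannot be seen, and folds of dim genes are compressed towards 1.

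Probe sets were named through the platform annotation. Of the probe sets, 34945 (77.6%) carry 1 gene symbol, 932 carry several and 9160 are unnamed here. Gene identifiers were matched to a reference gene table of assembly GRCm38.p6, used only for names: 34741 probe sets matched, 204 kept the platform's symbol and 0 symbols changed. No gene was named from a probe set with several symbols. Of 18193 named genes, each was represented by its probe set with the highest mean over all 8 arrays, and a gene was tested if that mean reached the 50th percentile of all probe set means, an intensity of 27.8. This left 10547 genes, and 7646 were too dim. Some genes of the fixed lists have no probe set of their own name and were not analysed here.

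Dark zone was compared with light zone using limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, Benjamini-Hochberg adjusted p under 0.05). Every difference is the dark zone mean minus the light zone mean on the log2 scale, with the moderated standard error. The median standard error was 0.07. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists with at least 5 tested members. Of these, 14 passed. With an estimated correlation 6 passed: both zone profiles, NF-kB, MHC class II, ribosome biogenesis and G2/M. With fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 22 passed. Values of single lists of markers were compared by exact permutation over the 70 arrangements of the arrays.

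Before the data were examined, 30 gene lists were fixed from general knowledge, which includes published light zone and dark zone profiles that may rest on these samples. Named genes are the genes of the gate, the 10 largest positive and 10 largest negative differences among genes past the threshold whose arrays did not overlap, up to 4 members with the largest differences in each list, and a set of genes fixed by name. Other list members are named where they moved against the rest of their list. A list of monocyte genes used in the closing section was written after the data were examined. The planned comparison of control probe sets for RNA degradation was not run, because no such probe sets are in the table used here (0 were found).

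The pipeline was tested on simulated data with the levels and spread of the 10547 tested genes, of which 200 were changed by known amounts. For the comparison of dark zone with light zone, it recovered 25.4% of 67 genes changed by 0.25 on the log2 scale, 100% of 67 changed by 0.5 and 100% of 66 changed by 1, and 5.06% of its 158 calls were unchanged genes. In a simulation of 26 lists it found the 1 list shifted by 0.5 and called 0 others. The simulation drew genes independently, so it does not test the effect of correlation between genes. It also changed far fewer genes than the 4629 that passed in the data, which makes the adjusted threshold stricter than in the data. The shares recovered therefore do not carry over to the real comparison.

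Alternatives varied the filter, the probe set that stands for a gene, the normalization, the variance model, array weights, the replicate number as a block, the threshold, the gene list test and the arrays included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.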

Results

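Gene expression was measured in germinal centre B cells from the lymph nodes of C57BL/6 mice, 12 days after immunization under the skin with NP-KLH, a hapten coupled to a carrier protein, in alum. Germinal centres are the sites where B cells proliferate, mutate their antibody genes and are selected by antigen and T cells. They are divided into a dark zone, classically the site of division and mutation, and a light zone, where B cells meet antigen and follicular helper T cells. Cells were sorted into these 2 populations, and total RNA of each sorted sample was hybridised to 1 Affymetrix mouse array. There were 8 arrays, 4 labelled light zone and 4 labelled dark zone, and the labels call the samples biological replicates. The median intensity per array lay between 27.3 and 28.1, and no pair of arrays held identical values. The number of arrays limits the precision of every comparison.

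The labels describe the light zone gate as high in CXCR4 and low in CD83, and the dark zone gate as the reverse, which is opposite to the usual definition of the populations. The mRNA of both genes followed the zone titles instead of the gate wording. Cd83, a surface protein of activated B cells, had an intensity of 7381.5 ± 194.9 (SD, n = 4) in the arrays labelled light zone and 1478.2 ± 111.2 (SD, n = 4) in those labelled dark zone, a log2 difference (dark minus light) of -2.32 with a standard error (SE) of 0.07 (limma adjusted p = 8.1e-10). Cxcr4, the receptor for CXCL12, had an intensity of 803.9 ± 39.2 (SD, n = 4) in light zone arrays and 1571.1 ± 125.5 (SD, n = 4) in dark zone arrays, a difference of 0.96 (SE 0.07, limma adjusted p = 5.7e-07). All 4 arrays of each title lay on the same side for both genes. Groups were taken from the titles, so every direction that follows is between arrays labelled dark zone and arrays labelled light zone. Fas, which encodes CD95, and Ptprc, whose B220 isoform marks B cells, were also part of the gate. Their differences were -0.23 and -0.21, and a dimmer probe set of Ptprc gave -0.73. Genes of the gate check the labels and are not findings.

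**Figure D1:**
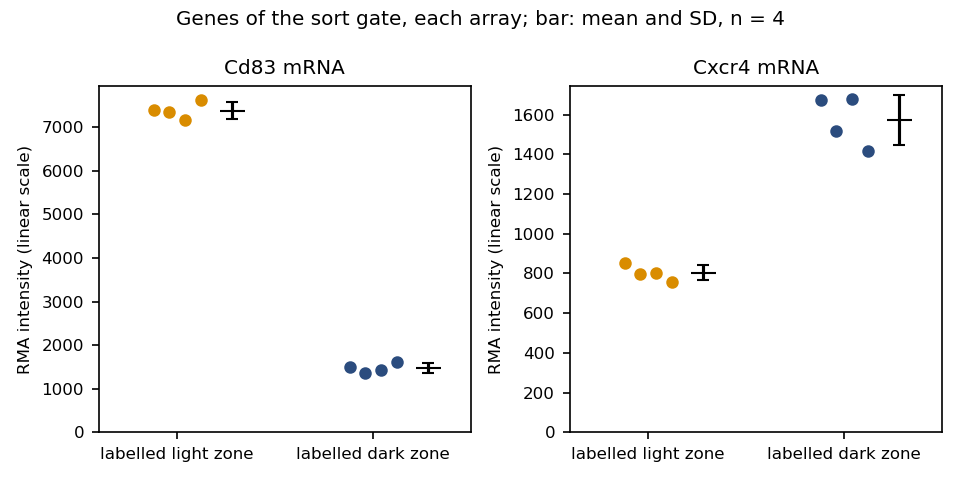
RMA intensity on a linear scale (y axis) of Cd83 (left) and Cxcr4 (right) in each array, by the zone in the sample title (x axis). Points are single arrays and the bars are the mean and SD of 4 arrays. Cd83 lay between 7158 and 7631 in light zone arrays and between 1363 and 1624 in dark zone arrays, and Cxcr4 was higher in every dark zone array.

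The populations differed in a large part of the genome. Of 10547 genes bright enough to test, 4629 (43.9%) passed a limma adjusted p of 0.05 after Benjamini-Hochberg correction. Of these, 2015 were higher in the dark zone and 2614 in the light zone. Most differences were small. A difference of at least 1.5-fold was reached by 407 genes higher in the dark zone and 653 higher in the light zone, and at least 2-fold by 123 and 207. In 4360 genes (41.3%) the 4 arrays of each title did not overlap, where chance gives 2.86%. Arrays of the same title correlated at 0.995 to 0.997 across the tested genes, and arrays of different titles at 0.974 to 0.980. The first principal component held 77.3% of the variance and separated the titles.

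The gene with the largest difference was Egr3, a transcription factor induced by antigen receptor signalling, at -4.67 (SE 0.10, limma adjusted p = 6.2e-11). A dimmer probe set of Egr3 gave 0.01. Next came the G1 cyclin Ccnd2 (-3.74, SE 0.17), the chemokine receptor Ccr6 (-3.53, SE 0.12), the homeobox factor Hhex (-3.02, SE 0.14) and the cytokine receptor Lifr (-2.98, SE 0.11). The other genes among the 10 highest in the light zone by this measure were Serpinb1a (-2.83), Egr2 (-2.67), Snn (-2.64), Serpinb6b (-2.62) and Plscr1 (-2.57). The genes with the largest rise in the dark zone were Lyz1 (3.58, SE 0.52) and Lyz2 (2.98, SE 0.46), which encode lysozymes. Their values varied widely between arrays of a title, with an SD of 1.21 and 1.14 among dark zone arrays against a median of 0.10 over all tested genes, and the Lyz1 probe set is of a type that can also detect related transcripts. A Lyz1 probe set of another type gave 0.18 and was near the floor. Lyz2 was on a list of myeloid markers. The mean of the other 18 genes of that list, 5 of them above the filter, was higher in the dark zone by 0.09. Lyz1 and Lyz2 were followed by the cell cycle regulator Rgcc (2.92, SE 0.11) and the receptor tyrosine kinase Ret (2.84, SE 0.13). Then came the sodium channel gene Scn11a (2.40, SE 0.09) and the glycosyltransferase gene Gcnt3 (2.38, SE 0.09). The remaining 4 of the 10 were Lgr5 (2.31), Reln (2.31), Selenop (2.27) and Otub2 (2.27). A dimmer probe set of Lgr5 gave 0.38. In the population where they were lower, 6 of these genes had a mean below the level of the filter, near the floor of the arrays: Lifr (mean log2 3.84), Ret (4.04), Plscr1 (4.37), Gcnt3 (4.42), Scn11a (4.67) and Ccnd2 (4.73). Differences are understated there, so the order of these genes among the others is not settled.

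**Figure D2:**
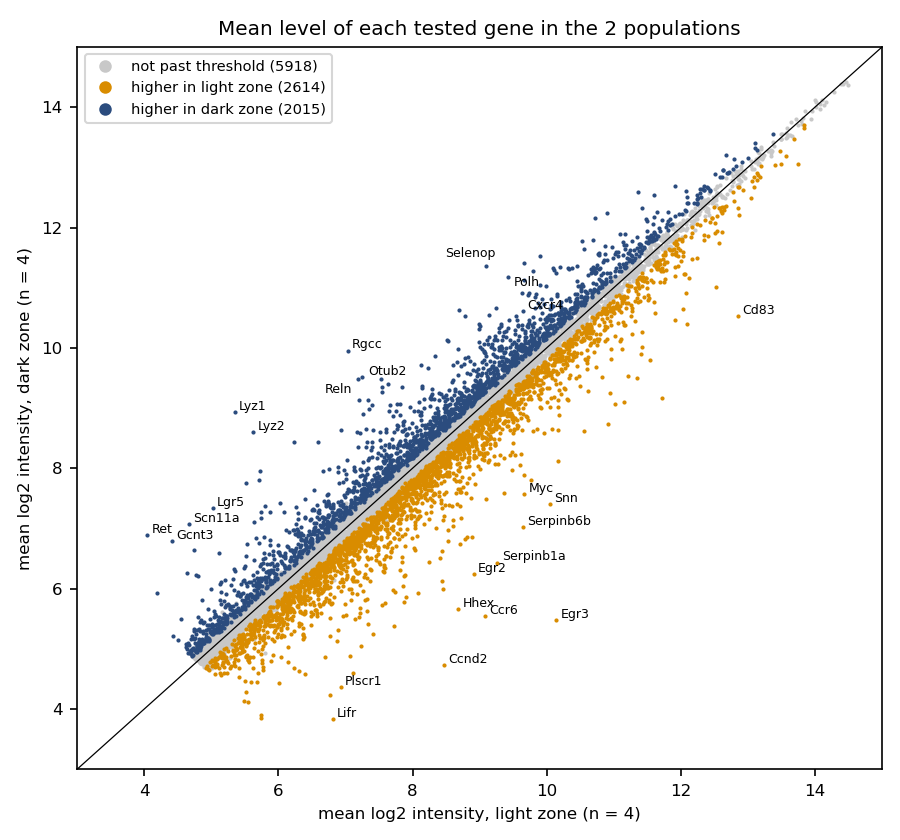
Mean log2 intensity of each of the 10547 tested genes in the 4 light zone arrays (x axis) and the 4 dark zone arrays (y axis). Points above the diagonal are higher in the dark zone. Blue and orange mark the 2015 and 2614 genes past the limma threshold, and labels mark the 20 genes with the largest differences together with Myc, Cd83, Cxcr4 and Polh.

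Nearly all tested genes of late cell cycle phases were higher in the dark zone. Of 43 tested genes of the G2 and M phases, 42 were higher in the dark zone and none was lower (43 higher when adjusted over the list alone). The median difference was 0.95 (camera adjusted p = 1.5e-29, and adjusted p = 0.033 with an estimated correlation). The mitotic kinesin Kif20a rose by 1.96 (SE 0.09), the centrosomal kinase Nek2 by 1.75 (SE 0.08), the B-type cyclin Ccnb2 by 1.64 (SE 0.06) and the kinetochore protein Cenpf by 1.60 (SE 0.07). Mki67, a general proliferation marker, rose by 0.53 (SE 0.07). Genes of DNA replication and the G1 to S transition moved much less. Of 30 tested, 10 were higher in the dark zone, 3 were lower and 17 did not pass (10 and 3 adjusted over the list alone), with a median of 0.10. Mcm4 (0.33), Pole (0.31) and Dtl (0.31) rose, while the thymidylate synthase gene Tyms fell by 0.45. The rises of Dtl and Mcm4 rest on their brightest probe set: none of the 4 dimmer ones of Dtl (-0.08 to 0.26) passed, nor did the 1 of Mcm4 (0.01). Without light zone replicate 1 or 3, or dark zone replicate 1, only 1 gene of this list was lower. The camera adjusted p of this list was 0.043, and the adjusted p was 0.30 with an estimated correlation. The call was also lost when light zone replicate 1 (adjusted p = 0.084) or 2 (0.060), or dark zone replicate 2 (0.057), 3 (0.062) or 4 (0.051), was left out, and when each array was centred on its median (0.058). The mean shift of the G2 and M list exceeded that of the replication list by 0.87 (two-sided exact permutation test over the 70 arrangements of 4 against 4 arrays, p = 0.0286, the smallest it can give). Among 15 regulators of G1, 6 were higher in the dark zone and 4 in the light zone (the same counts adjusted over the list alone), with a camera adjusted p of 0.41, a median of 0.06 and a mean of -0.15, so median and mean differed in sign. Without light zone replicate 2 or 3, only 2 of them were higher in the light zone. The D-type cyclins moved apart, with Ccnd2 at -3.74 and Ccnd3 at 0.64 (SE 0.06). The Cdk inhibitor Cdkn2d (0.45) and Ccng2 (0.45) were higher in the dark zone.

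Genes of the NF-kB pathway were mostly higher in the light zone, while immediate early genes went both ways. Of 18 tested genes of the NF-kB pathway and its targets, 16 were higher in the light zone and none in the dark zone (17 adjusted over the list alone), with a median of -1.18 (camera adjusted p = 4.7e-12, and adjusted p = 0.0098 with an estimated correlation). They included the inhibitors Nfkbid (-2.10, SE 0.12) and Nfkbia (-1.51, SE 0.06), the subunit gene Relb (-1.81, SE 0.09), Bcl3 (-1.83, SE 0.09) and the feedback regulator Tnfaip3 (-1.53, SE 0.06). Of 23 immediate early genes, which respond quickly to receptor signals, 13 were higher in the light zone and 4 in the dark zone (14 and 4 adjusted over the list alone), with a median of -0.70. The camera adjusted p was 3.5e-04, and the adjusted p was 0.068 with an estimated correlation. Egr1 (-1.96, SE 0.11), Egr2, Egr3, Myc (-2.10, SE 0.13) and the activation marker Cd69 (-2.03, SE 0.10) led this group. Btg2 (0.73), Klf6 (0.64), Dusp5 (0.41) and Nr4a3 (0.17) moved the other way. The call of the gene Nr4a3 was lost when any array other than light zone replicate 4 or dark zone replicate 4 was left out (limma adjusted p = 0.057 to 0.114).

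Genes through which B cells present antigen and engage T cells were mostly higher in the light zone. In the MHC class II pathway, 14 of 16 tested genes were higher in the light zone and 1, the protease gene Lgmn (0.32), in the dark zone (the same counts adjusted over the list alone). The median was -0.44 (camera adjusted p = 2.2e-06, and adjusted p = 0.036 with an estimated correlation). The largest differences were in the thiol reductase gene Ifi30 (-1.70, SE 0.06), the class II transactivator Ciita (-1.15, SE 0.07) and H2-Oa (-0.98, SE 0.06). Of 18 genes for contact with T cells and response to their cytokines, 12 were higher in the light zone and 1, Slamf6 (0.52), in the dark zone (14 and 1 adjusted over the list alone), with a median of -0.38. The camera adjusted p was 6.1e-05, and the adjusted p was 0.084 with an estimated correlation. Slamf1 (-1.68, SE 0.06), Cd40 (-1.53, SE 0.06), the costimulatory ligand Cd86 (-1.30, SE 0.07) and the adhesion molecule Icam1 (-0.98, SE 0.08) led this list. In a list of migration and adhesion genes, 15 of 24 were higher in the light zone and 5 in the dark zone (16 and 5 adjusted over the list alone), with a median of -0.28, a camera adjusted p of 0.0041, and an adjusted p of 0.087 with an estimated correlation. Gpr183, a receptor that guides B cells by oxysterols, was at -2.17 (SE 0.10) and Rgs1 at -1.06 (SE 0.12). Plxnb2 (0.50), S1pr4 (0.36) and Gna13 (0.32) were higher in the dark zone. Of 13 genes of naive and memory B cells, 8 were higher in the light zone and 2, Nt5e (1.53) and Cd44 (0.24), in the dark zone (9 and 2 adjusted over the list alone). The median was -0.71 with a camera adjusted p of 0.0010 and an adjusted p of 0.22 with an estimated correlation. Its leading members were Ccr6, Hhex, Gpr183 and the IgE receptor gene Fcer2a (-2.06, SE 0.06).

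Growth and metabolic genes did not all move one way. Of 27 tested genes of ribosome biogenesis and MYC targets, 24 were higher in the light zone and none in the dark zone (24 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 7.5e-09, and adjusted p = 0.012 with an estimated correlation). They included the spermidine synthase gene Srm (-1.38, SE 0.07) and the nucleolar protein gene Gnl3 (-1.21, SE 0.06). Genes of the ribosomal proteins themselves were largely level: 13 of 17 did not pass, 3 were higher in the light zone and 1 in the dark zone (2 higher in the light zone adjusted over the list alone; camera adjusted p = 0.79). The 1 was lost when any array other than light zone replicate 4 was left out. In cholesterol synthesis, 13 of 16 genes were higher in the light zone and none in the dark zone (13 adjusted over the list alone), with a median of -0.54. The camera adjusted p was 5.6e-05, but the adjusted p was 0.29 with an estimated correlation, which was 0.50 for this list. Insig1 (-0.95, SE 0.09), Dhcr7 (-0.91, SE 0.09) and the regulator Srebf2 (-0.74, SE 0.10) were among them. In glycolysis, 8 of 15 genes were higher in the light zone and 1 in the dark zone (10 and 1 adjusted over the list alone), with a median of -0.26, a camera adjusted p of 0.020, and an adjusted p of 0.087 with an estimated correlation. The call was also lost when the probe sets of each gene were averaged (adjusted p = 0.060). The glucose transporter gene Slc2a3 (-1.02, SE 0.08) and the lactate transporter gene Slc16a1 (-0.90, SE 0.08) were higher in the light zone, and the pyruvate kinase gene Pkm (0.44, SE 0.09) in the dark zone. In oxidative phosphorylation, 11 of 26 genes were higher in the dark zone and 3 in the light zone (12 and 5 adjusted over the list alone), with a median of 0.13. The camera adjusted p was 0.032, the adjusted p was 0.16 with an estimated correlation, and it was 0.073 with averaged probe sets. Atp5b (0.80, SE 0.09) and Uqcrc1 (0.61, SE 0.09) rose most.

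**Figure D3:**
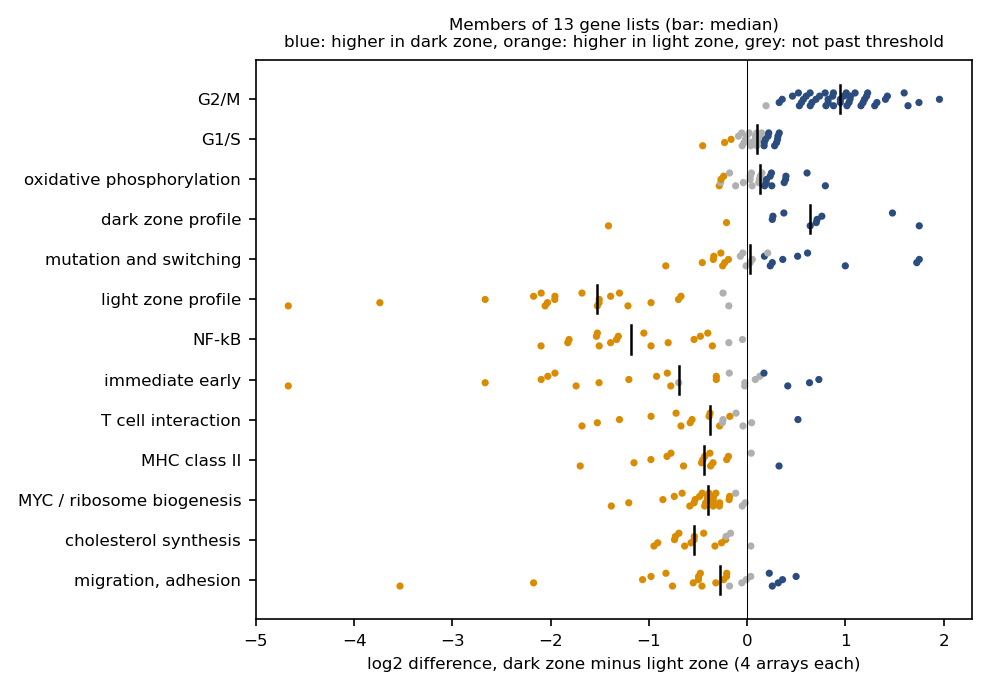
Log2 difference, dark zone minus light zone (x axis), of each tested member of 13 gene lists (y axis), from 4 arrays of each title. Points are genes, coloured by whether they passed the limma threshold and in which direction, and black bars are medians. The G2/M list lies to the right, with a median of 0.95, and the NF-kB list to the left, with a median of -1.18.

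Lists drawn from published profiles of the zones followed the titles. These profiles may rest on these same samples, so the counts are not independent evidence of direction. The lists also overlap with others tested here. Nfkbia, Cd40, Icam1, Egr1, Myc, Slamf1, Cd86, Gpr183 and Fcer2a of the light zone list recur in the NF-kB, immediate early, T cell, migration or naive and memory lists. Polh, Foxo1 and Bach2 of the dark zone list recur in the mutation or identity lists. Results of these lists are therefore not separate from each other. Of 21 genes listed for the light zone, 19 were higher in the light zone and none in the dark zone (21 adjusted over the list alone), with a median of -1.53 (camera adjusted p = 5.4e-18, and adjusted p = 0.0023 with an estimated correlation). Of 11 genes listed for the dark zone, 9 were higher in the dark zone, and Lmo2 (-1.41, SE 0.07) and Rgs13 (-0.21) were higher in the light zone (9 and 2 adjusted over the list alone). The call of the gene Rgs13 was lost when any array other than light zone replicate 1 was left out (limma adjusted p = 0.058 to 0.110). Its value was -0.13 without light zone replicate 2. The median of the dark zone list was 0.64 (camera adjusted p = 3.0e-04, and adjusted p = 0.033 with an estimated correlation). Polh, the error-prone DNA polymerase eta, rose by 1.75 (SE 0.07), Gcsam by 1.48 (SE 0.06) and Mybl1 by 0.76 (SE 0.10). The transcription factor genes Foxo1 (0.26, SE 0.06, limma adjusted p = 0.0054) and Bach2 (0.37, SE 0.07, limma adjusted p = 0.0010) rose less.

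Genes of antibody gene mutation and class switching did not pass as a list. Of 23 tested, 9 were higher in the dark zone and 8 in the light zone (the same counts adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.19. The count higher in the light zone depended on single arrays: it was 4 without dark zone replicate 1, and 5 without light zone replicate 2 or 4 or dark zone replicate 2. Polh, the ligase gene Lig4 (1.73, SE 0.07) and Poli (1.00, SE 0.08) rose, while the base excision repair gene Apex1 was at -0.83 (SE 0.08). Of 20 genes of homologous recombination, 7 were higher in the dark zone and 2 in the light zone (the same counts adjusted over the list alone; camera adjusted p = 0.11). Eme1 (0.39, SE 0.07) and Fanci (0.37, SE 0.07) were among those higher in the dark zone. The count higher in the light zone was 0 without light zone replicate 1 or dark zone replicate 2, and 1 without light zone replicate 2 or 3 or dark zone replicate 3 or 4. Of 21 genes of germinal centre and B cell identity, 9 were higher in the dark zone and 6 in the light zone (the same counts adjusted over the list alone; camera adjusted p = 0.18). Tcf3 rose by 0.71 (SE 0.06), and Pou2f2 was at -0.58 (SE 0.09). Bcl6, the master regulator of germinal centre B cells, was at 0.14 (SE 0.07, limma adjusted p = 0.13), and Pax5 was at 0.22 (SE 0.13, limma adjusted p = 0.18), or 0.13 without light zone replicate 3 or dark zone replicate 3. Both passed when their probe sets were averaged, at 0.39 (limma adjusted p = 0.0015) and 0.40 (limma adjusted p = 0.0011). Of 22 genes of the B cell receptor complex and its signalling, 10 were higher in the light zone and 4 in the dark zone (the same counts adjusted over the list alone; camera adjusted p = 0.11, and 0.015 with no filter on dim probe sets). The inhibitory co-receptor genes Cd72 (-1.69, SE 0.08) and Cd22 (-0.66, SE 0.06) were higher in the light zone, and the kinase genes Syk (0.65) and Btk (0.59) in the dark zone.

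Genes of plasma cells, cell death, interferon response and heat shock did not pass as lists. Of 16 plasma cell genes, 8 were higher in the light zone and 4 in the dark zone (the same counts adjusted over the list alone; camera adjusted p = 0.11). This list passed towards the light zone with no filter on dim probe sets (adjusted p = 0.0089) and with averaged probe sets (0.016). The transcription factor genes Irf4 (-2.03, SE 0.09) and Prdm1 (-1.37, SE 0.12, from a dark zone mean of 4.13 below the level of the filter) were higher in the light zone, while Slamf7 (0.68, SE 0.10) and Cd93 (0.60) were higher in the dark zone. Of 17 apoptosis genes, 6 were higher in the light zone and 3 in the dark zone (7 and 3 adjusted over the list alone; camera adjusted p = 0.20). The survival gene Bcl2 was at -1.44 (SE 0.12) and the death-promoting gene Bid at -0.95 (SE 0.06), whereas the death-promoting gene Bcl2l11 rose by 0.92 (SE 0.06). Of 15 interferon-induced genes, 4 were higher in the light zone and 1, Ifit2 (0.19), in the dark zone (4 higher in the light zone adjusted over the list alone; camera adjusted p = 0.14, and 0.041 with no filter), with Usp18 at -0.54 (SE 0.09). The call of the gene Ifit2 was lost when any array other than dark zone replicate 2 or 3 was left out (limma adjusted p = 0.053 to 0.130). Of 11 heat shock genes, 2 were higher in each population (the same counts adjusted over the list alone; camera adjusted p = 0.83), with a median of 0.02 and a mean of -0.11. Without light zone replicate 2 or dark zone replicate 1, 1 was higher in the dark zone. The endoplasmic reticulum chaperone gene Hspa5 was at -0.53 (SE 0.06), and 1 of its 3 probe sets went the other way (0.33). The only further probe set of Btg2 did not pass (0.11), nor did 1 further probe set each of Bid (-0.03), Ccnd3 (0.07), Cd44 (-0.04), Nt5e (0.09) and Slamf6 (0.28), all named above by their brightest. In other named genes a dimmer probe set passed but differed from the brightest by more than 0.5 of its value. It was smaller in size for Ciita (-0.27), Nt5e (0.70), Nek2 (0.85) and Bcl2 (-0.69). It was larger for Polh (2.64), Gna13 (1.15), Ccng2 (1.03), Slamf6 (1.01), Foxo1 (0.71), Bcl6 (0.65) and Pax5 (0.58), and Syk had both (0.29 and 1.13).

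Markers of other cell types were compared as the mean log2 level of each list per array, with two-sided exact permutation tests whose smallest possible p is 0.0286. Over 8 lists tested this way, that smallest value has a Benjamini-Hochberg adjusted p of 0.0457. The mean of 19 myeloid genes was higher in the dark zone by 0.24 (exact permutation p = 0.0286), and without Lyz2 the other 18 were higher by 0.09 (exact permutation p = 0.0286). The mean of 16 T cell genes was lower in the dark zone, at -0.04 (exact permutation p = 0.0286), and the mean of 13 stromal genes was at 0.01 (exact permutation p = 0.71), with a range of -0.01 to 0.02 over the arrays left out and a sign that turned without light zone replicate 1 or 3 or dark zone replicate 2. The mean of 10 erythroid, platelet and natural killer cell genes was at 0.07 (exact permutation p = 0.057). Only 6 of the 16 T cell, 6 of the 19 myeloid, 4 of the 13 stromal and 2 of these 10 genes were above the filter, so the means of these lists rest mostly on probe sets near the floor. The median difference over all 18193 named genes, dim ones included, was 0.019, against -0.006 over the 10547 tested ones. The first value pools dim and tested genes, so the median of the dim genes alone lies above 0.019. Small rises in the means of these lists were not corrected for this shift of dim genes. The 17 plasma cell genes were at -0.34 and the 14 naive and memory genes at -1.04, the 28 immediate early genes at -0.72 (each exact permutation p = 0.0286) and the 13 heat shock genes at -0.09 (exact permutation p = 0.26), or -0.05 without light zone replicate 4 and -0.06 without dark zone replicate 2. The naive and memory genes had the largest shift of the 8 lists, and 13 of them were above the filter. Whether other B cells in the light zone samples contribute to this shift was not tested. As lists among all tested genes, T cell markers (1 of 6 higher in each population, the same counts adjusted over the list alone) and myeloid markers (2 of 6 higher in the dark zone and 1 in the light zone, the same counts adjusted over the list alone) had camera adjusted p of 0.79 and 0.39. For T cell markers the median was -0.01 and the mean 0.05, and without dark zone replicate 4 the number higher in the dark zone was 2. Cd2 (0.70, SE 0.10) and Lat (-0.52, SE 0.07) were the T cell markers that passed. Lyz2 had an intensity of 37.7 to 89.1 in light zone arrays and of 128.2 to 824.2 in dark zone arrays. The gene Csf1r, which encodes a receptor of monocytes and macrophages, was at 0.40 (limma adjusted p = 0.023) by its brightest probe set, and its other 2 probe sets gave 1.39 and 0.10. Its call was lost without light zone replicate 1 (limma adjusted p = 0.066) or 2 (limma adjusted p = 0.051), and its value was 0.26 without dark zone replicate 4.

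**Figure D4:**
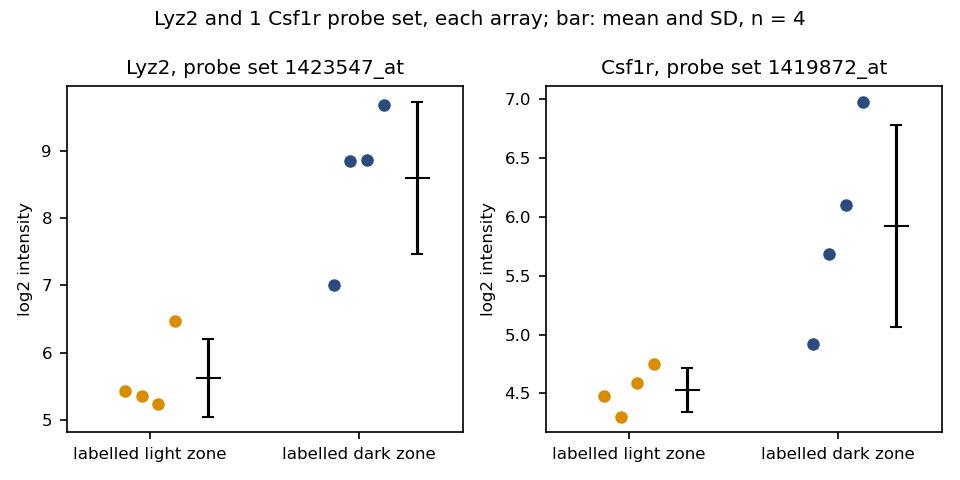
Log2 intensity (y axis) of Lyz2 (left) and of the Csf1r probe set with the largest difference (right) in each array, by the zone in the sample title (x axis). Points are single arrays and the bars are the mean and SD of 4 arrays. Lyz2 had an SD of 0.58 in light zone arrays and 1.14 in dark zone arrays, and the Csf1r probe set was higher in the dark zone by 1.39.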

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

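The tests of swapped titles, of carried-over cells, of probe sets shared by Lyz1 and Lyz2 and of a single array were chosen only after the result was seen.

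The gate wording and the mRNA of the gate genes ran in opposite directions. If the titles had been swapped between the groups, genes of division, textbook features of the dark zone, would be lower in arrays labelled dark zone, but the median of the G2 and M list was 0.95 higher there, which argues against a swap. The gate genes make up the pattern and so cannot test the wording. A gate that truly ran as worded would place cells of the usual dark zone definition in the samples labelled light zone. Genes of division would then be higher there, so the same median argues against such a gate as well. Surface protein was not measured here, so a wording reversed in the labels was not shown directly.

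Lyz1 and Lyz2 were higher and more variable in arrays labelled dark zone, where their SD ranked 1 and 3 among 10547 tested genes. Monocytes or macrophages are a candidate source, although the B220 and CD95 gate would remove them, and carried-over cells would make other myeloid genes follow Lyz2 from array to array within a title. For the 18 other myeloid genes fixed at the outset, 5 of them bright enough to test, the median within-title correlation with Lyz2 lay at percentile 81.8 of 10000 random lists matched on level; a second list of 31 monocyte genes, 16 of them bright enough to test, was written after the first had been looked at gene by gene and found mixed, and after a search for genes that follow Lyz2, whose hits it leaves out, and lay at percentile 99.5. A verdict needed both lists, members went both ways (9 of 18 and 21 of 31 correlated above 0 with Lyz2, Csf1r and Wfdc17 among them and Cd36 not), and the most abundant ones (Ifi27l2a at a mean log2 of 11.94, Cybb at 11.74) were too bright in these cells to show a small share of others, so carried-over cells cannot be told apart from expression by the B cells, which was not tested. Whether the Lyz1 probe set detects Lyz2 cannot be told either, since the Lyz1 probe set without shared sequence (0.18) was near the floor in every array. The Lyz1 probe set used for the gene ordered the arrays as Lyz2 did. Both were lowest in light zone replicate 3 (log2 4.75 and 5.24) and highest in dark zone replicate 4 (10.17 and 9.69). Detection of Lyz2 by that probe set and a joint rise would both give this, so Lyz1 and Lyz2 may not be separate results.

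G2 and M genes rose in the dark zone more than replication genes did. Compression of bright probe sets would shrink the difference once genes are matched on level. Each replication gene was matched to the G2 and M gene nearest in level, and the same G2 and M gene could serve in several pairs. Over 29 pairs matched within 0.5 on the log2 scale the median difference was 0.70 (quartiles 0.49 and 0.93), which argues against compression as the whole cause. A single array is also argued against, since the difference of 0.87 between the mean shifts stayed at 0.84 to 0.89 when any array was left out. Biological explanations, such as a different share of cells in each phase or different transcript levels within a phase, were not tested and stay open.

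The splits of the arrays argue against chance for the count of genes, but cannot exclude it. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 4629 genes. The highest of the others gave 0. A share of 1 in 35 is the smallest these splits can give. Each other split also mixes the titles, so that the zone difference enters its spread and holds its count down. For the gene lists, only 1 split, the real one, gave 14, but the highest of the others gave 13. The 16 splits that move 1 array of each title across still hold part of the zone difference and gave 5 to 13 lists, whereas the 18 splits with 2 arrays of each title on each side gave 0 to 2. The list count is therefore a weak measure of how well the arrays separate.

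Single arrays stood apart from the other 3 of their title in 11 of 292 groups of 4 values (3.77%), measured as the gap to the nearest array over the whole range, and chance alone gives about 1 in 20. Dark zone replicate 1 was high for Gimap4 (0.893). In light zone replicate 1, Bcl2 (ratio 0.835) and H2-Oa (0.877) were above the others. Light zone replicate 3 was low for Gpr183 (0.867), and light zone replicate 4 was high for Lyz2 (0.847). Dark zone replicate 2 was low for Scn11a (0.842) and high for the mean of the plasma cell list (0.833). Dark zone replicate 4 was high for Csf1r (0.856) and low for Nek2 (0.886), Plscr1 (0.840) and Ret (0.889).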

How the results depend on the processing

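The alternatives with Lyz2 as a covariate, without both arrays numbered 4, and with the myeloid list less Lyz2 were chosen after seeing the data. The count of genes that differ (4629) moved by more than 1.5 times only where features were counted or called by another rule. Every probe set on its own gave 9182 (4352 higher in the dark zone, 4830 in the light zone), at least 1.5-fold gave 1060 (407 and 653), and at least 2-fold gave 330 (123 and 207). At an adjusted p under 0.01, 3205 genes passed, with 1316 higher in the dark zone. The filters gave 3519 to 4678 genes, the other ways to choose probe sets of a gene 4447 and 4509, the variance model and array weights 4754 and 4720, the covariate 4758 and the 6 arrays not numbered 4 3925. Leaving out 1 array gave 4092 to 4340 genes (1706 to 1914 and 2342 to 2509). Centring arrays on their median gave 4566 and quantile normalization again 4625, with 37.9% and 45.8% of calls higher in the dark zone against 43.5%. Of the 26 lists, 14 passed with the preset correlation, 6 with an estimated correlation, 22 with fry, which asks another question, and 13 to 14 with 1 array left out. T cell markers turned towards the light zone with no filter (adjusted p = 0.455), as did heat shock with averaged probe sets (0.792), with fry (0.725) and without light zone replicate 1 (0.961) or dark zone replicate 4 (0.952), within 0.627 to 0.962 over the arrays left out. These lists passed under none of those settings, and the cause was not tested. Over the alternatives, values of single named genes kept direction and side of the threshold in 3015 comparisons, lost a call in 79, gained 1 in 13 and reversed in 0, and single lists did so in 407, 17, 12 and 5. Many of these genes were named for large differences past the threshold, so their agreement is partly built in. Further probe sets on their own, apart from Ptprc, were not in this count. The Hspa5 probe set that passed the other way (0.33) is therefore not among the reversals. With the replicate number as a block (replicate block), 4787 genes passed (2088 and 2699), 5040 with trend and robust settings as well, and 13 lists, without the G1 to S list (adjusted p = 0.053). The labels do not say that a number marks a shared animal or day. Deviations of same-numbered arrays from their group means correlated at 0.126, 0.189, 0.0596 and 0.243 across genes, which are not independent replicates, so 1 of 4 lay under 0.1 and the numbers were not taken as pairs. As a hint towards pairing, 7 of 8 arrays correlated best with their own number, the exception being dark zone replicate 3 with light zone replicate 1 (0.0909). Of 12 correlations between different numbers, 10 were below 0. Deviations within a title sum to 0, so positive correlations at the same number push the others below 0. The negative correlations are therefore not a separate hint. The planned test of RNA degradation was not run. Signal over background limits dim genes: near the floor of the arrays differences are understated, and 7646 genes were too dim to test.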

Other observations

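Families of genes that share a symbol stem were examined after the main results were seen, with camera at the preset correlation over 180 stems of at least 8 tested genes, and 7 stems passed. Of 8 tested Gimap genes, which encode small GTPases of lymphocytes, 7 were higher in the light zone and none in the dark zone (median -0.46, camera adjusted p = 0.017, and adjusted p = 0.80 with an estimated correlation), led by Gimap4 (-1.74, SE 0.08) and Gimap7 (-0.67, SE 0.07). Of 11 genes with the stem Irf, interferon regulatory factors and their binding proteins, 8 were higher in the light zone and none in the dark zone (median -0.36, camera adjusted p = 0.017, and adjusted p = 0.64 with an estimated correlation), among them Irf1 (-0.52) besides Irf4. Of 14 Dennd genes, whose products activate Rab GTPases of vesicle traffic, 10 were higher in the light zone, including Dennd11 (-1.08, SE 0.10) and Dennd4b (-0.89, SE 0.08), and 1, Dennd1b (0.29, with -0.14 and 0.69 by other probe sets), in the dark zone. The median was -0.39, with a camera adjusted p of 0.017 and an adjusted p of 0.64 with an estimated correlation. Of 12 Snhg genes, long transcripts that host small nucleolar RNAs, 9 were higher in the light zone and none in the dark zone, or 1 without light zone replicate 2 (median -0.43, camera adjusted p = 0.023, and adjusted p = 0.80 with an estimated correlation), led by Snhg4 (-0.89, SE 0.11) and Snhg3 (-0.88, SE 0.13). The other 3 stems were higher in the dark zone. Several of the 24 kinesin genes (stem Kif) are on the G2 and M list, Kif20a among them, so this stem partly repeats that result. Of the 24, 13 were higher in the dark zone and 2 in the light zone (median 0.19, camera adjusted p = 5.9e-04, and adjusted p = 0.64 with an estimated correlation). That 2 was 0 without light zone replicate 4 or dark zone replicate 2, and 1 without light zone replicate 1 or 2 or dark zone replicate 3 or 4. The stem Cdc mixes cell division genes, some of them also on the G2 and M list, with Cdc42 and its effectors. Of its 31 genes, 12 were higher in the dark zone and 2 in the light zone, or 1 without light zone replicate 4 (median 0.14, camera adjusted p = 0.017, and adjusted p = 0.64 with an estimated correlation). Of 34 centrosomal protein genes (stem Cep), 15 were higher in the dark zone and 4 in the light zone (median 0.16, camera adjusted p = 0.023, and adjusted p = 0.80 with an estimated correlation). The genes named here, other than Irf4 and Kif20a, were chosen after their values were seen.

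Probe sets with no single gene name also differed. Of 3668 such probe sets bright enough to test, 1355 (36.9%) passed a limma adjusted p of 0.05, with 530 higher in the dark zone and 825 in the light zone, against 40.8% of all 22519 probe sets bright enough to test. Their identity was not analysed here.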
